A study of Mus musculus with 2 samples.

How the data were processed

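Gene expression was measured in full-thickness back skin of male C3H/HeN mice, 61 days old, on 2 single-colour Agilent arrays, 1 of FGF18-injected and 1 of PBS-injected skin. Per the labels' protocols, RNA was extracted with a phenol-based reagent, poly(A) RNA was selected on oligo(dT) columns, and Cy3-labelled cRNA was made from 200 ng. The design text says that RNA was pooled within each group, whereas the extraction protocol says that mice were extracted separately; with pooled RNA the spread between mice cannot be measured. Groups were taken from the source names. Both arrays lay on 1 slide and came from 1 scan, so neither slide nor scan differed between the groups.

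Per the file headers, the scanner images were read with Agilent Feature Extraction 9.5.3.1 under protocol GE1-v5_95_Feb07 for array design 014868. The deposited intensity values include the spot's mean intensity, its local background and a processed signal, which per the file headers is background-subtracted and detrended, with values near background replaced by a surrogate. The deposited files also hold other columns, per the file headers: flags for spots well above background, saturated spots and outliers, spot types and spot numbers. The series value table holds the authors' values as a ratio: set against the scanner files, each column was the processed signal divided by that array's median over all spots (83.8 for FGF18 and 80.0 for PBS), on a linear scale and in the same direction, with a largest departure of 0.0072 on the log2 scale. Its column medians were 1.00 and 0.999, and 7 and 2 missing values were the spots marked as non-uniform. Any scaling between arrays by the authors beyond this is not given in the sources used here. Each array had 45018 spots, of which 1639 were controls, and 0 columns of sample values were left unmapped.

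For the main setting, log2 of the processed signal was taken and each array's 75th percentile of it (a signal of 1020 for FGF18 and 899 for PBS) was subtracted. Control spots and outlier-flagged spots were left out, replicate spots of a probe were averaged, and a probe counted as measured where a share of at least 0.5 of its spots was well above background. Of 41165 probes, 24338 were measured on both arrays, 1013 on the FGF18 array only and 671 on the PBS array only. The log2 ratios of different probes of a gene were averaged. For a gene measured on 1 array only, the bright value was set against the higher of the dim array's own value and its floor, the lowest signal among probes well above background (23.3 for FGF18 and 24.2 for PBS), and is given as "at least" a fold. Signals near this floor limit what dim genes can show; the negative controls had a median signal of 5.74 and 6.03. Names were updated through a RefSeq gene table of assembly GRCm38.p6, used for names alone: 23368 probes were named by accession, 6732 by symbol and 2907 by an older synonym, and 8158 kept the name in the files. The files name no genome build, so no coordinates are given.

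With 1 array per group no test was made and no p-value is given. Genes were counted at a fold of 2 or more. For 36 gene lists of hair follicle compartments, skin cell types, FGF signalling and cell states, the median log2 ratio of the measured members (at least 5) was set against 10000 random lists of the same size drawn from the same 20 bins of mean expression. The percentile describes these arrays and is no test of the treatment. Technical error was taken from probes printed as at least 8 spots, in 3 classes of signal.

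The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule took, among genes with a plain symbol, the 12 highest and 12 lowest ratios of genes with a mean signal at or above the median of detected genes, all probes well above background on both arrays and all probes changed the same way. It further took the 4 largest bounds in each direction, the 4 leading members of each list outside the central 95% of its random lists, the highest and lowest member of other lists at most, and 26 genes of FGF signalling, the cell cycle and the hair cycle in every case. Some genes that the rule took are not reported here. Genes named outside this rule are marked in the text as chosen after their values were seen, and those in the closing section's added lists were all chosen so.

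The alternatives were scaling to the median, no scaling, quantile normalization, loess between the arrays, the 75th percentile of detected probes, normexp background correction with an offset of 50, the series value table, other filters on dim probes (1 array, none, a signal over 100), saturated probes left out, the brightest or the median probe of a gene, thresholds of 1.5 and 3, random lists without matching, list means, and lists without genes shared between lists. Scaling to 7 spike-in (E1A) probes and 9 added lists were chosen after seeing the data. Scaling by a constant (the median, none, the 75th percentile of detected probes, spike-ins) and leaving out saturated probes cannot change a list's percentile. The series value table, a signal over a constant, can change it little. Counts of alternatives below include these. The computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1. The calculation was tested on simulated data for the FGF18 and PBS comparison with 16610 genes: 4.5% of 200 unchanged lists fell outside the central 95%, 98.0% of lists shifted by 0.25 were above it, 50 of 50 genes shifted by 1.5 and 50 of 50 shifted by -1.5 were counted at 2-fold, and 0 of 16410 unchanged genes were. For the lists, ratios were shuffled among genes of like expression and members were drawn independently, so the share of unchanged lists outside was nearly fixed in advance. Genes of a real list can vary together, so neither list share carries over to the lists below. For the gene counts, both simulated arrays had the same levels with a small fixed probe noise and no variation between mice. The 0 follows from that setting. It is no estimate of false calls in the data, where log2 ratios had an SD of 0.40.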

Results

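FGF18 is a secreted fibroblast growth factor that is made in the hair follicle. The series asked which transcripts of mouse back skin were affected when FGF18 protein was delivered locally during anagen, the growth phase of the hair cycle. Anagen had been started in C3H/HeN males by plucking the hair, and 1 µg of FGF18, or phosphate-buffered saline (PBS) in its place, was injected under the skin on day 4. Full-thickness skin was taken 24 h later, 5 days after depilation, from mice 61 days old. The labels name 3 mice without saying whether this is the number per group. According to the design text, poly(A) RNA was pooled within each group, and 1 single-colour Agilent whole mouse genome array was used per group. The title of the PBS sample carries the word telogen, the resting phase, whereas its source name and its hair cycle entry give anagen; it is called the PBS array here. Of 43379 probe spots per array, 27050 (62.4%) were well above background on the FGF18 array and 26665 (61.5%) on the PBS array, and 0 spots were saturated. With 1 array per group, the difference between the arrays has no replicate check, and the number of arrays limits the precision of every value below. Technical error alone could be measured from 179 probes printed as 10 spots each. The SD of a single spot's log2 ratio had a median of 0.11 for dim, 0.041 for middle and 0.026 for bright probes.

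Genes of the interferon response were higher on the FGF18 array, with a median of 4.66-fold, and genes of keratin-associated proteins, which fill the hardening hair shaft, were lower, with a median of 4.44-fold. Genes of the inner root sheath, the shaft keratins and the epidermal barrier were lower by smaller amounts, and those of DNA replication and mitosis were at nearly the same level on both arrays. Of 16610 genes measured on both arrays, 256 were at least 2-fold higher and 164 at least 2-fold lower on the FGF18 array, together 2.53% of genes. At 4-fold, 75 genes were higher and 23 lower. The log2 ratio of all genes, FGF18 minus PBS, had a median of -0.07 and an SD of 0.40, and the log2 signals of the arrays correlated at r = 0.987 across genes, which are not independent replicates. Of the genes past 2-fold, 61.0% were higher. This share depended on the scaling between the arrays: it was 64.1% to 72.7% with the other planned scalings, 78.5% without any scaling and 99.0% with scaling to spike-in transcripts. It also depended on the filter and the threshold. The share was 46.8% without a filter on dim probes, 54.1% with genes of 1 array included and 72.1% with signals over 100. At a threshold of 1.5 it was 44.1%, and at 3 it was 73.1%. The list medians below are scaled log2 ratios, to be read against the -0.07 of all genes rather than against 0, and each percentile compares a list with other genes of the same arrays.

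**Figure D1:**
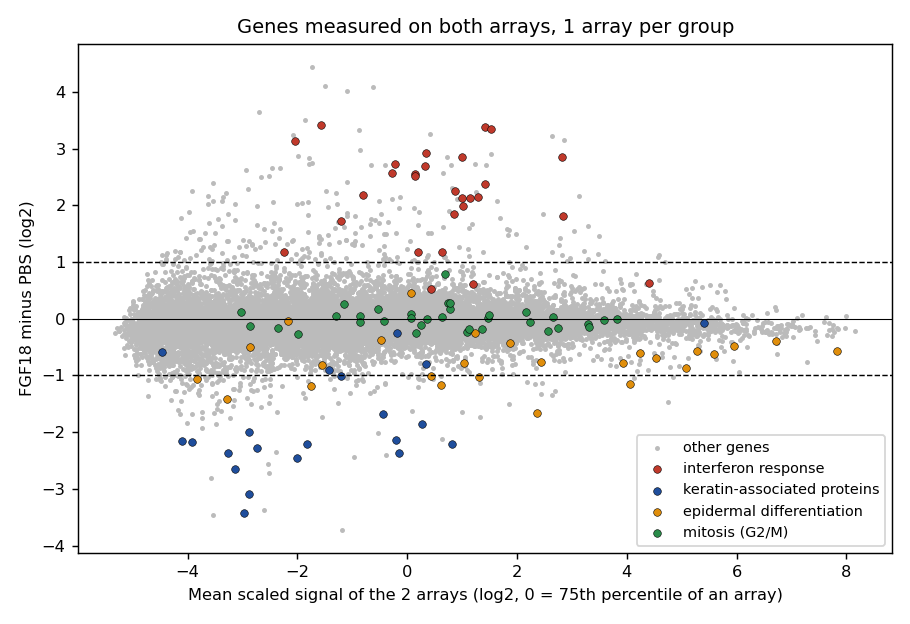
Log2 ratio, FGF18 minus PBS, against the mean scaled log2 signal for the 16610 genes measured on both arrays; each point is a gene and dashed lines mark 2-fold. Interferon-response genes (median 2.22) lie above and keratin-associated protein genes (median -2.15) below the cloud, while mitotic genes (median -0.01) lie within 2-fold; these positions relative to the cloud hold with every scaling tried.

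The interferon-response list had a median log2 ratio of 2.22 over 28 measured genes, above all 10000 random lists matched on mean expression, as a description of these arrays. Of the 28 genes, 25 were at least 2-fold higher and 0 lower; the other 3, Irf1, Stat2 and Ifi27, were 1.44-, 1.53- and 1.54-fold higher and were named after their values were seen. Rsad2, which encodes the antiviral enzyme viperin, was 10.6-fold higher, Ifit3 10.4-fold and Ifit1 6.66-fold. The GTPases of cell-autonomous immunity included Tgtp1 (10.2-fold), Igtp (9.39-fold), Mx1 (8.83-fold) and Iigp1, whose processed signal was 19500 on the FGF18 array and 2370 on the PBS array (7.25-fold). Irf7, a transcription factor that amplifies interferon production, was 7.20-fold higher. Cxcl10, a chemokine that draws activated T cells and NK cells, was 7.56-fold higher, and Cxcl11, which binds the same receptor, was at least 26.3-fold higher, being not well above background on the PBS array. Ms4a4c (log2 ratio 3.32), Slfn4 (3.25), Phf11a (2.91) and Phf11d (2.86) were also among the 12 highest ratios of bright genes with all probes well above background on both arrays, of which Gzmb was first. Tgtp1 was left out of these 12 because it had another probe that did not meet this condition. The list stood above the central 95% of its random lists in 17 of 17 alternatives, though scaling by a constant cannot change this position.

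Immune cell genes went both ways. Gzmb, the protease granzyme B of cytotoxic lymphocytes, was 21.7-fold higher on the FGF18 array (signal 1430 against 58.1), and Gzma was at least 19.1-fold higher. Acod1, an enzyme that makes itaconate in activated macrophages, was at least 17.5-fold higher. The list of T cell and dendritic cell genes as a whole had a median of -0.15 over 17 genes (percentile 11.4), with Cd207, the langerin of Langerhans cells, lowest at -0.74. Its mean, with Gzmb among the members, was 0.14 (percentile 96.6). The macrophage list had a median of -0.19 over 20 genes (percentile 0.59), but its mean was 0.25 (percentile 99.7), which lay above the random lists. Its 4 members at least 2-fold higher were Fcgr1 (6.57-fold), Ccl2 (4.94-fold), Ccl7 (4.45-fold) and Msr1 (2.93-fold), named after their values were seen. Arg1 and Retnla, markers of alternatively activated macrophages, were 2.57- and 2.21-fold lower, and Mrc1 was 1.63-fold lower. The neutrophil list had a median of -0.07 over 8 genes (percentile 54.2), in which S100a8 was 3.53-fold higher and Cxcr2 1.52-fold lower, and 3 more members were measured on the FGF18 array only. Its position depended on dim genes: with genes of 1 array included the median was 0.31 over 11 genes (percentile 99.8), and with signals over 100 it was 0.89 over 5 (percentile 100). Its mean was 0.29 (percentile 98.3). Mast cell genes had a median of -0.06 over 9 genes (percentile 50.1), with Hdc, the histamine-forming decarboxylase, 2.79-fold higher.

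Keratin-associated protein genes had a median log2 ratio of -2.15 over 21 measured members, below all 10000 random lists. Of these, 16 were at least 2-fold lower on the FGF18 array and 0 higher. Another 11 members were measured on the PBS array only, at least 2.34-fold to at least 12.3-fold lower on the FGF18 array, and with these at their bounds the median over 32 members was -2.21. Krtap22-2 was 10.7-fold lower, Krtap28-13 8.55-fold, Krtap21-1 6.30-fold and Krtap6-1 5.45-fold, all at dim signals on the FGF18 array. Among brighter members, Krtap5-1 was 5.16-fold lower, Krtap17-1 4.60-fold, Krtap6-3 4.39-fold and Krtap5-4 3.62-fold. Krtap4-16, Krtap4-7, Krtap9-3 and Krtap5-2 had the largest bounds of the PBS array, at least 12.3-, 11.1-, 9.30- and 8.37-fold. Members of this family are similar in sequence, so a probe can also bind transcripts of its relatives. The median was -1.44 with normexp background correction and -1.43 over the 12 members with a signal over 100 on both arrays.

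Shaft keratin and hair matrix genes had a median of -0.40 over 20 genes, below all random lists, with 5 at least 2-fold lower and 0 higher. Those 5 were Krt34 (log2 ratio -2.44), Krt33b (-1.63), Krt33a (-1.32), Krt82 (-1.32) and Krt31 (-1.05), keratins of the hair shaft; Krt31 was named after its value was seen. In the same list Lef1, a Wnt-pathway transcription factor of the hair matrix, was at -0.33, and Krt35, Krt85, Msx2 and Hoxc13, also named afterwards, lay between -0.02 and 0.07, while Krt32, Foxn1 and Prdm1, likewise named afterwards, were at -0.80, -0.72 and -0.48. Inner root sheath genes, which encode the layer that moulds the shaft, had a median of -0.49 over 15 genes, below all random lists. Krt26 (2.31-fold) and Tchh (2.10-fold), the gene of trichohyalin, were at least 2-fold lower, and Krt27 and Padi1 were 1.79- and 1.63-fold lower. Tchh was just under 2-fold (-0.99 to -0.87) with median scaling, no scaling, quantile normalization, loess, normexp and the series value table. The companion layer and inner bulge list was at -0.27 over 9 genes (percentile 1.02), with Sbsn 2.03-fold (2 probes at -1.39 and -0.65) and Krt6b 1.37-fold lower. It kept this position in 15 of the 16 alternatives with enough measured genes and lost it with quantile normalization.

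**Figure D2:**
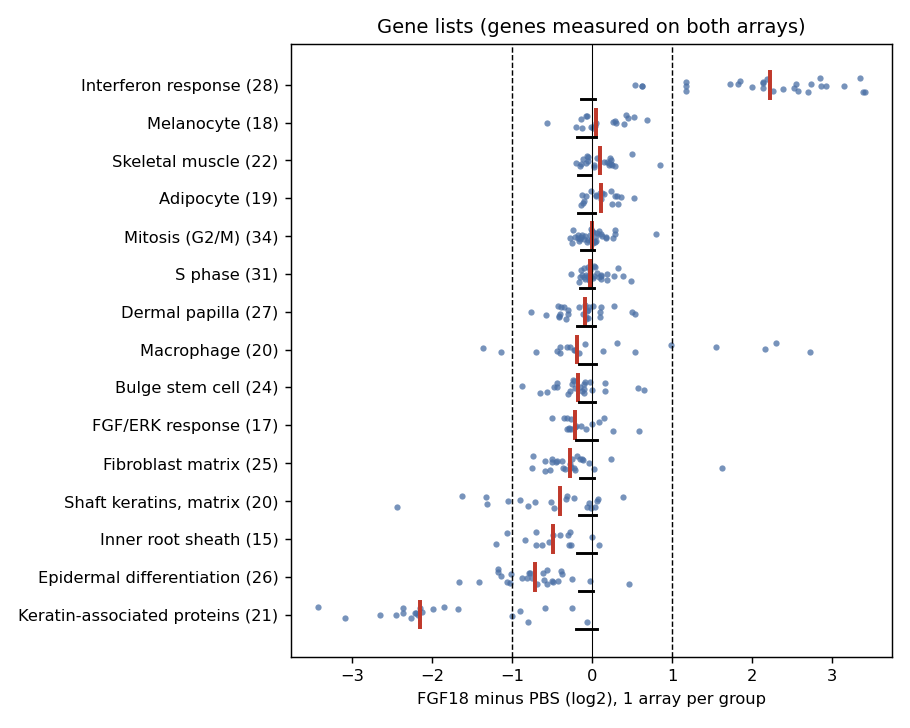
Log2 ratio, FGF18 minus PBS, of the members of 15 gene lists fixed before the data were examined; each point is a gene measured on both arrays, the number measured stands in parentheses, red bars are medians and black bars the central 95% of the medians of 10000 random lists. The medians run from 2.22 for the interferon response to -2.15 for keratin-associated proteins; scaling to spike-in transcripts would move every point right by 0.81, and the medians of the lists under 0, other than keratin-associated proteins, to values over 0.

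Genes of epidermal differentiation, which build the cornified barrier, had a median of -0.72 over 26 genes, below all random lists, with 8 at least 2-fold lower and 0 higher. Sprr1a was 3.17-fold lower, Rptn 2.67-fold, Sprr2h 2.27-fold and Casp14, a protease of the cornified layer, 2.26-fold. The basal keratins Krt5 and Krt14 were at -0.06 and 0.02. The list of wound and inflammation genes of keratinocytes had a median of -0.28 over 21 genes (percentile 0.07) and a mean of -0.03. Sprr1b and Ereg were 2.09- and 2.03-fold lower, at dim signals on the FGF18 array (49.9 and 58.1). Both were under 2-fold with median scaling, no scaling, quantile normalization, loess, normexp and the series value table. With genes of 1 array included, or without a filter on dim probes, Ereg was at -0.43. Krt6a was at -0.08, while Saa3 (12.6-fold), S100a8 (3.53-fold) and Slpi (2.47-fold) were higher, Saa3 and Slpi being named after their values were seen. Sebaceous gland genes had a median of -0.04 over 14 genes (percentile 77.2), with Awat2 at -0.91 and Scd1 at 0.36. Melanocyte genes had a median of 0.04 over 18 genes (percentile 96.7), with the pigment enzyme gene Tyr at 0.69, at dim signals of 51.5 and 28.1, and Ednrb at -0.57.

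In the dermis and below it, fibroblast matrix genes were lower by a small amount, at a median of -0.28 over 25 genes and below all random lists. The collagen genes Col1a2 and Col1a1 were at -0.75 and -0.74, Col3a1 at -0.60 and Col5a1 at -0.58. The separate probes of Col1a1 ranged from -1.13 to -0.31, and the 2 probes of Col3a1 were at -1.03 and -0.16. Timp1, a secreted inhibitor of matrix proteases, was 3.07-fold higher and the only member past 2-fold, and it was named after its value was seen. Skeletal muscle genes had a median of 0.10 over 22 genes (percentile 100), led by Actn3 (1.80-fold higher) and Atp2a1 (1.41-fold higher). Adipocyte genes were also at 0.10, over 19 genes (percentile 99.9), with Thrsp 1.43-fold and Retn 1.28-fold higher. The smooth muscle list was at 0.12 over 13 genes (percentile 99.5), with Des 1.19-fold higher, but lost this position in 3 of 17 alternatives. No member of these muscle and fat lists was past 2-fold. Endothelial genes had a median of 0.08 (percentile 97.3), with the VEGF receptor gene Kdr at 0.58 and Sox7 at -0.40, nerve and Schwann cell genes -0.09 (percentile 44.0), with Gfap at -0.74 and Mbp at 0.17, and erythrocyte genes 0.11 (percentile 93.0), with Hba-a1 at 0.54 and Slc4a1 at -0.66.

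Genes that respond to FGF receptors through the ERK kinases showed no member past 2-fold. Their list had a median of -0.22 over 17 genes (percentile 1.38), and it was below the central 95% of its random lists in 11 of 17 alternatives. These include scalings by a constant, which cannot change that position. Dusp6, a phosphatase induced by ERK, was at -0.32, Spry2 at -0.14, Etv4 at -0.26, Etv5 at -0.29, Egr1 at -0.35 and Phlda1 at -0.50. In the other direction, Fos was at 0.59 and Myc at 0.26, both named after their values were seen, and Spry4 was measured on the FGF18 array only, at least 1.28-fold higher. Among FGF ligands and receptors (median -0.05 over 17 genes, percentile 62.8), Fgf18 itself was at -0.41, at signals of 194 and 228. Fgf5, which ends anagen, was at -0.43, Fgf7 at 0.54 and Fgf10 at -0.05. Fgfr1, Fgfr2, Fgfr3 and Fgfr4 were at 0.17, 0.04, -0.19 and -0.34. Fgf22 was at -1.63, at dim signals of 55.3 and 151.

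Genes of the cell cycle differed little. The S phase list had a median of -0.02 (percentile 85.4) with 0 of 31 genes past 2-fold, and the mitotic list -0.01 (percentile 88.0) with 0 of 34. Cdk1 was highest among mitotic genes at 0.80, Top2a lowest at -0.27, and Mki67 was at -0.15. Ccnd1 was at -0.20, Ccne2 at 0.48 and E2f2 at -0.26. The list of CDK inhibitors and p53 targets had a median of -0.05 (percentile 53.2), with Cdkn1a at -0.21 and Gadd45a at 0.74.

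Among signals that steer the hair cycle, 4 lists lay inside the range of their random lists. Dermal papilla genes had a median of -0.10 (percentile 35.2), Wnt genes -0.12 (percentile 12.4), BMP and TGF-beta genes -0.12 (percentile 18.2) and Hedgehog genes -0.08 (percentile 39.6). The Wnt list lay below its random lists with the brightest probe of each gene (median -0.21, percentile 0.17) and as a mean (-0.18, percentile 1.74). In these lists Igfbp3 was at -0.77 as the mean of 2 probes that disagreed, at -1.42 and -0.12. Ccn5 was at 0.60, Bmp8a at -0.93, Tgfb3 at 0.51, Gli1 at 0.19 and Boc at -0.30. Shh was at -0.14, Bmp4 at 0.00 and Bmp6 at 0.08. Bulge stem cell genes had a median of -0.18 over 24 genes (percentile 1.40), a position kept in 13 of 17 alternatives. Lgr5 was 1.83-fold and Sox9 1.57-fold lower. Genes that regulate catagen, the regression phase, had a median of -0.25 over 19 genes (percentile 0.53), kept in 11 of 17 alternatives. Il1a was 2.46-fold lower at dim signals, Tgfb2 1.76-fold and Stat3 1.71-fold lower, and Ccl2 4.94-fold higher. The 2 probes of Stat3 were at -1.05 and -0.49.

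Of the remaining lists, immediate early and stress genes had a median of -0.10 (percentile 32.5), with Atf3 2.02-fold higher and Jund 1.52-fold lower. Hypoxia and glycolysis genes were at -0.02 (percentile 84.9), with Ankrd37 at -0.50, and housekeeping genes at -0.06 (percentile 67.8), with Sdha at 0.31 and Polr2a at -0.33. Actb was at -0.26 and Gapdh at 0.29, the latter at signals of 64.6 and 46.5 that are far below those of an abundant transcript. Ribosomal protein genes had a median of -0.19 (percentile 1.19), kept in 14 of 17 alternatives. Cholesterol and lipid synthesis genes were at 0.04 (percentile 97.9), kept in 9 of 17, with Lss 1.54-fold and Idi1 1.30-fold higher. In all, 12 of 36 lists lay below and 5 above the central 95% of their random lists, where 1.80 would lie outside by chance if the genes of a list varied independently, which co-regulated genes do not.

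The 12 lowest ratios among such bright genes also held some outside the hair lists. Lmnb1, which encodes lamin B1 of the nuclear envelope, was 4.34-fold lower, Glyr1 3.31-fold and Arl6ip5 3.12-fold, each by 1 probe. Slc16a6 was 5.28-fold and Barx2, a homeobox gene, 4.06-fold lower as means over probes that disagreed: the 2 probes of Slc16a6 stood at -4.35 and -0.45, and the 3 probes of Barx2 between -2.90 and -0.51. Among 74 genes past 2-fold with several probes, 50 had all probes past 2-fold and 2 had probes on opposite sides of 0. Genes measured on a single array numbered 610 for FGF18 and 402 for PBS, of which 127 and 154 had a bound of at least 2-fold. Scaling to 7 spike-in probes would add 0.81 to every log2 ratio; whether equal spike-in amounts went with equal RNA is not given in the sources used here, so the meaning of this shift is unknown. The medians of the epidermal differentiation, inner root sheath, shaft keratin and fibroblast lists would then be 0.09, 0.32, 0.41 and 0.53, and that of keratin-associated proteins -1.34.

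**Figure D3:**
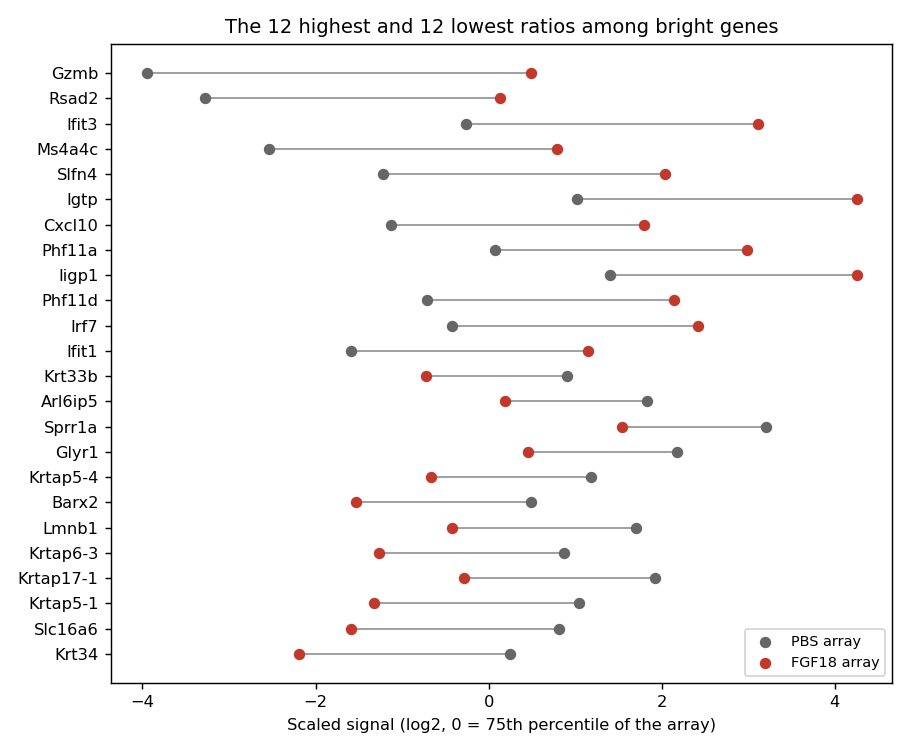
Scaled log2 signal (0 is the 75th percentile of an array) on the PBS array (grey) and the FGF18 array (red) for the 12 highest and the 12 lowest ratios among bright genes with all probes well above background on both arrays, 1 array per group. Gzmb lies 4.44 apart and Krt34 -2.44; scaling to spike-in transcripts would add 0.81 to each difference, with all 24 keeping their sign.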

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

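Scaling to spike-in transcripts was chosen after the results were seen; the other alternatives were planned. No paired analysis was possible because the groups share only 1 replicate number, and leaving out a replicate or blocking by slide was not run, with 1 array per group and both arrays on 1 slide. Leaving out saturated probes moved nothing because 0 spots were saturated. Low signal over background limits the dim genes, and much of the movement below came with filters on them or with normexp, which adds an offset to dim signals by construction. The cause of the other changes was not tested.

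The counts at 2-fold (256 higher, 164 lower) became 167 and 68 with normexp and 2677 and 28 with spike-in scaling. Without a filter on dim probes they were 790 and 897. They were 336 and 92 without scaling, 383 and 325 with genes of 1 array included, and 181 and 70 with signals over 100. At a threshold of 1.5 the counts were 630 and 800, and at 3 they were 117 and 43. The genes of a single array past the bound (127 FGF18, 154 PBS) became 16 and 42 with normexp, 413 and 40 with spike-in scaling, 224 and 303 at a threshold of 1.5, and 41 and 56 at 3. Lists above the central 95% of random lists numbered 3 with the brightest probe, and lists below it numbered 7 with list means. The median log2 ratio of all genes, -0.07, was 0.74 with spike-in scaling, 0.11 without scaling, 0.03 with median scaling, 0.04 with the authors' value table and -0.18 without a filter, so lists are given relative to it here.

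On that scale the interferon list (2.29) was at 2.21 with normexp, 2.23 with genes of 1 array included and 2.499 without a filter. Keratin-associated proteins (-2.08) were at -1.35 with normexp, -1.37 with signals over 100 and -1.77 as a mean. Shaft keratins (-0.33) were at -0.26 with genes of 1 array included, -0.14 without a filter, -0.41 with signals over 100, -0.51 as a mean and -0.42 without shared genes. Epidermal differentiation (-0.65) was at -0.55 with normexp, -0.54 without a filter and -0.59 with signals over 100. The inner root sheath (-0.42) was at -0.31 without a filter. These 5 lists and the fibroblast, skeletal muscle and adipocyte lists stayed outside their random lists on the same side in 17 of 17 alternatives. With constant scalings and without saturated probes this outcome was fixed in advance, and nearly so with the authors' value table. Only the other alternatives tested it.

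Without a filter, the values were 0.0091 for FGF and ERK genes, 0.042 for the bulge, -0.093 for the companion layer, -0.0067 for catagen, -0.093 for wound genes, 0.28 for skeletal muscle, 0.28 for adipocytes, -0.10 for fibroblasts, -0.042 for macrophages, 0.30 for smooth muscle, -0.026 for ribosomal proteins and 0.17 for cholesterol synthesis; the first 2 changed sign. As means, wound genes (0.044) and macrophages (0.32) changed sign, and FGF and ERK genes were at -0.055, catagen at -0.028 and smooth muscle at 0.071. Without shared genes, catagen changed sign (0.026) and wound genes were at -0.36. With quantile normalization, ribosomal proteins changed sign (0.011) and skeletal muscle was at 0.24; with loess, ribosomal proteins were at -0.070. With the brightest probe, FGF and ERK genes were at -0.014, catagen at -0.069, smooth muscle at 0.019 and cholesterol synthesis at 0.040. Smooth muscle was at 0.12 with normexp, fibroblasts at -0.28 with genes of 1 array included and catagen at -0.062 with signals over 100. Of the 19 lists inside the range of their random lists, 4 left it in 10 cases: neutrophil, melanocyte and endothelial genes to the higher side in 3, 2 and 3 alternatives and Wnt genes to the lower side in 2. The other 244 values of the 17 lists outside moved by less than the SD of random lists. Of 47 named genes past 2-fold, 26 stayed past it throughout, and 649 of 649 values kept their sign, of which 592 were past 2-fold. Slc16a6 was at -0.45 and Barx2 at -0.51 with the brightest probe.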

Other observations

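The added gene lists in this part and all tests in it were chosen after the results were seen. Beyond interferon-response genes, cytotoxic lymphocyte genes were higher on the FGF18 array, at a median log2 ratio of 1.41 over 7 genes. Ccl5, a chemokine of activated lymphocytes, was 6.52-fold higher, Prf1, the pore-forming perforin, 3.34-fold and Klrk1, the receptor NKG2D, 2.65-fold, while Gzmc was 1.49-fold lower. Klrk1, whose value is the median, had dim signals of 120 and 39.9, and Gzmb and Prf1 were dim on the PBS array (58.1 and 56.2). At higher signals, Klrd1 and Nkg7 were at 1.00 and 0.83. This list was not put through the alternatives. The NK cell receptor genes Ncr1 and Klrb1c were measured on the FGF18 array only. The T cell receptor complex genes Cd3e and Cd3g were at -0.45 and -0.49, Cd3e at dim signals of 76.4 and 91.8. Other T cell genes went both ways: Cd4 and Cd2 were at -0.68 and -0.16, at dim signals, and Lck was at 0.38. Of the interferon genes themselves, Ifng and Ifnb1 were measured on the FGF18 array only, at least 2.37- and at least 2.77-fold higher, and Ifnl3 was at -0.46. Ifna2, Ifna4, Ifna5 and Ifnk were not well above background on either array, and other interferon genes were not analysed here. Bounds from dim signals depended on the background correction: with normexp, 16 in place of 127 genes of the FGF18 array alone had a bound of at least 2-fold.

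Antigen presentation genes differed by class. MHC class I presentation genes had a median of 0.53 over 12 genes (percentile 100), with the immunoproteasome gene Psmb10 2.02-fold, the peptide transporter gene Tap1 1.74-fold and H2-K1 1.40-fold higher, whereas class II genes had a median of -0.20 over 8, inside the range of their random lists (percentile 5.79). With spike-in scaling, which adds 0.81 to every ratio, both medians would be over 0. Markers of alternatively activated macrophages had a median of -0.47 over 13 genes, from -1.36 for Arg1 to -0.07 for Clec10a; Ccl24 was 1.64-fold and Cd209a 1.63-fold lower. The spike-in signals themselves differed: the 7 probes well above background on both arrays were lower on the FGF18 array after scaling, at a mean of -0.81 (SD 0.094, range -0.92 to -0.67), so they were 1.76-fold brighter on the PBS array.

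The interferon-response genes were higher on the FGF18 array than any other fixed list. A like increase of all immune cells of the kinds in the PBS skin is argued against as the whole cause. Leukocyte genes did lie above all random lists (median 0.27, percentile 100), with Hcls1 2.17-fold and Cd53 2.09-fold higher. Their upper quartile was 0.57, however, where the interferon list had a median of 2.22. That list mixes markers of several cell kinds (lower quartile -0.28), so it cannot exclude more cells of a single kind. Cytotoxic lymphocyte genes had a median of 1.41 over 7 genes, which was the value of Klrk1 at dim signals. Incoming cells already in an interferon-driven state were not tested. A constant scaling moves all genes alike, so it could not change the list's median relative to all genes, 2.29. Quantile normalization, loess and normexp, which could change it, gave 2.27, 2.27 and 2.21, the last being the lowest over all alternatives. These values argue against signal-dependent scaling and background correction as the cause. Another component of the injected protein solution, such as bacterial lipopolysaccharide, cannot be told apart from FGF18, because no other protein was injected. Genes of the lipopolysaccharide response had a median of 0.11 over 14 genes, above the central 95% of random lists (percentile 98.6). That median leaves out 4 more measured on the FGF18 array only, where 0 were measured on the PBS array only. They were at least 17.5-fold (Acod1), 4.48-fold (Ccl3), 1.51-fold (Lcn2) and 1.37-fold (Cxcl1) higher. A response of the skin to FGF18, and a response of 1 mouse where RNA was pooled, both remain possible and untested.

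Late hair shaft genes were lower on the FGF18 array. Fewer hair bulbs in the FGF18 skin are argued against as the whole cause, since the pigment cell genes of the bulb had a lower quartile of -0.076, against a median of -2.15 for keratin-associated proteins. Pigment cell genes near the floor, such as Tyr, could show little loss, but over 15 members with signals over 100 the median was 0.01. Inner root sheath genes were lower, at a median of -0.49, so a smaller loss of bulbs is not excluded. Probe sequence shared within the keratin-associated protein family may let its members move together and stays open, since the probes could not be compared by sequence. The shaft keratin and matrix list, fixed beforehand and outside the family, was lower by less, at a median of -0.40. Another hypothesis that stays open is a later onset of terminal shaft differentiation, which may leave earlier genes less affected: early shaft genes had a median of -0.31, which is 1.02 above that of the late shaft keratins (-1.32), but both lists were written from knowledge of the values, so the difference decides nothing. Members overlapped: of 5 late keratins 3 were at least 2-fold lower, but Krt86 was at -0.51 and Krt36 at -0.06, while Krt82 of the early list was at -1.32. A difference in anagen stage between the skin pieces before the injection was not tested.

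The title of the PBS sample raises the question of whether that skin was in telogen. Mitotic genes, high in anagen follicles, would then be far higher on the FGF18 array, yet their upper quartile was 0.077. This value depends on the scaling: with spike-in scaling the mitotic median would be 0.80, though only 0.06 above that of all genes. Keratin-associated protein genes were higher on the PBS array with every scaling tried, so these values together argue against telogen. An exchange of the 2 arrays cannot be told apart from the stated order, since the injected protein carries no transcript of its own; the Fgf18 transcript was at -0.41.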
